A study of Mus musculus with 4 samples.

How the data were processed

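Total RNA of splenic T cells from male B6CASTF1/J mice was sequenced in 4 libraries of 1 group, with a stranded library kit and spike-in RNAs per the labels. Per the text deposited with each library, values refer to the mouse assembly mm10 and the GENCODE annotation M21. The names of the aligner and of the quantifiers are not given in the sources used here. The gene and transcript tables of the first quantification were derived from an alignment to the transcriptome and have the column layout of RSEM. A second transcript table was derived from 1 read file per library and has the column layout of kallisto.

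The deposited expected counts are estimates per gene or transcript, not normalized. The deposited TPM values divide each estimate by effective length and sum to the same fixed total over all targets, spike-ins and transfer RNA identifiers included, so abundant short RNAs lower the TPM of other genes. The deposited FPKM values scale to length and to the number of counted reads, per the file headers. The deposited percent values give the share of a transcript in its gene. Each library was quantified alone, with no pooling. Reads were assigned to the C57BL/6 reference, and reads that carry CAST/EiJ variants could be lost or moved to similar genes.

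The tables held 55536 mouse genes, all with a symbol in the M21 annotation, 26248 numeric identifiers and 97 spike-ins. The numeric identifiers name no gene, took at most 8.75e-05% of counts in a library and, like the spike-ins, stayed out of library sizes and tests. Spike-ins took 0.299% to 0.347% of counts. Totals were 15818334, 17335895, 16439475 and 14584388 counts in libraries 1 to 4. A floor of 3 counts corresponds to 0.190, 0.174, 0.183 and 0.206 CPM in these libraries. PCR reads without molecular identifiers are not independent molecules, so floors cover counting error only. Transcript values of the second quantification were summed per gene.

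Levels are given as deposited TPM with the mean and SD of 4 libraries. The level of a gene list is the mean of log2(TPM + 1) over its members, and differences between lists and log2 ratios of 2 genes were taken within each library and tested with an exact two-sided sign-flip permutation test over the 4 libraries, whose smallest p is 0.125. Because there is 1 group, no contrast between conditions was fitted. Variation between libraries was tested with edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with an intercept only, trended dispersion, TMM scaling, the filterByExpr filter and the goodness-of-fit test per gene, with Benjamini-Hochberg adjustment at 0.05. The filter kept 13118 genes, and it asks for counts in all 4 libraries, which removes genes high in a single library. The common biological coefficient of variation was 0.0938. On simulated counts for this 4-library test over 12879 genes, 72.9% of 96 genes changed 2-fold and 98% of 99 genes changed 4-fold in 1 library were called, and 1 of 12684 unchanged genes was. The simulated counts were drawn at the trended dispersion that the test assumes. These rates need not hold for real genes, whose dispersion can depart from the trend. The deviation of a list in a library is the mean over its tested members of the log2 CPM (prior count 2) minus the mean of the 4 libraries, set against 10000 random lists of the same size matched in 20 bins of mean expression. The two-sided p of each deviation against these lists, adjusted by Benjamini-Hochberg over 96 deviations, was added after the deviations had been seen. Lists and gene classes among the variable genes were tested with Fisher's exact test against the tested genes. This test counts genes as independent, so its p is not reliable where genes move together in 1 library. Python 3.11.15, scipy 1.17.1, pandas 2.3.3, limma 3.58.1 and DESeq2 1.42.0 were used, the last as an alternative. Some genes and a transcript that the rules for naming would have included are not reported here, though they remain in the list means and counts.

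The gene lists, the sign-flip and goodness-of-fit tests, the alternatives and the rule for named genes were set before the data were examined. Fisher's tests of lists and gene classes were not part of that plan. There were 27 lists: pan-T, CD4 and CD8 lineage, naive, effector and memory, regulatory, helper subset, gamma-delta, inhibitory receptor, transcription factor, B cell, plasma cell, natural killer, monocyte and macrophage, neutrophil, dendritic, erythroid, platelet, stroma and endothelium, proliferation, early response, interferon, housekeeping, non-polyadenylated RNA, Y-linked, X inactivation and imprinted genes. Of the listed symbols, 5 had no identifier. Named genes were the 10 protein-coding and 5 other nuclear genes with the highest mean TPM, the top 3 of each list (up to 6 for 5 of the lists), the members of each ratio, the genes studied for isoforms, Xist and the Y-linked genes, the 10 genes with the largest goodness-of-fit statistic and a mean TPM of at least 1, and the top 5 Trav and Trbv segments. A few further genes were named after their values were seen, namely Blk, Tcrg-C1, Trav7d-2, Fos, Fosb, Hspa1b, Mki67, Kcnq1ot1, Il17a and Tnfrsf17 in the report and those said to be so in the closing section.

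Alternatives covered each library left out, pseudocounts of 0.1 and 5, other filters, medians in place of means, FPKM, the second quantification, DESeq2 size factors and dispersion outliers, and a common dispersion. Detection with TPM rescaled to protein-coding and receptor genes was added after seeing the data. A comparison of libraries 3 and 4 with libraries 1 and 2 over one gene class was computed and left out, because those libraries had been put together by the level they were then compared on. The values of that class are given per library instead.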

Results

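Total RNA was measured in T cells from the spleen of male F1 mice, the offspring of a C57BL/6 mother and a CAST/EiJ father, at 66 days of age. The labels describe the cells by the antigen CD3, the signalling complex of the T cell receptor. There was 1 group of 4 biological replicates, called libraries 1 to 4 here after their replicate numbers, each made from 300 ng of RNA with synthetic spike-in RNAs added. The design holds no second condition, so the comparisons are between gene groups within a library and between the 4 libraries. The labels give 4 separate biological samples and 1 shared donor identifier, and do not say outright whether each sample is a separate animal. SDs and the p-values of the sign-flip and goodness-of-fit tests therefore concern the spread between these samples. The p-values of Fisher's test and of the random lists compare genes with other genes and do not measure that spread. Total estimated counts were 15818334, 17335895, 16439475 and 14584388 in libraries 1 to 4, and spike-ins took 0.325% ± 0.0211 of them (SD, n = 4).

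A total of 11653 genes had a TPM, the length-normalised transcript abundance, of at least 1 in every library. Short structural RNAs took a large part of the TPM. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle on chromosome 12, together held 27.1% ± 0.678 (SD, n = 4), and the quantification split the reads of these near-identical genes equally, so their separate levels are uncertain. Rn7sk, which restrains transcription elongation, stood at 61174 ± 1873 TPM, Rpph1, the RNA of ribonuclease P, at 14644 ± 322 TPM, and Rmrp at 14413 ± 385 TPM (SD, n = 4 each). Rmrp has 2 overlapping annotated genes and is uncertain as well, and the second deposited quantification gave it 0.00222 TPM. Gm26917, annotated as a long non-coding gene on chromosome 17 between 39843013 and 39846341 in mm10, took 12.4% ± 0.451 of all counts. Which RNA supplied these reads was not tested. Protein-coding genes held 64.9% ± 0.631 of counts but 35.4% ± 0.652 of TPM, since TPM divides by length. The non-polyadenylated RNA list had a mean log2(TPM + 1) of 9.20 ± 0.038. Among protein-coding nuclear genes the highest levels belonged to translation. Rps27, Rplp1, Rps29, Rps24, Rpl13a and Rps16 encode ribosomal proteins, and Rps27 led with 4045 ± 130 TPM. Eef1a1, a translation elongation factor, had 4019 ± 82.1 TPM and Tpt1 3238 ± 76.6 TPM, followed by Actb, cytoskeletal actin, at 2915 ± 105 TPM and H2-K1, an MHC class I heavy chain, at 1806 ± 86.8 TPM (SD, n = 4). The 82 ribosomal protein genes named Rpl or Rps plus a number, a set without Rplp1, together held 6.57% ± 0.194 of TPM. Genes of the mitochondrial chromosome held 7.12% ± 0.243 of counts, of which the 2 mitochondrial ribosomal RNAs made 6.23% ± 0.217 of all counts. The housekeeping list stood at 8.55 ± 0.037 on the log2(TPM + 1) scale.

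T cell genes dominated the cell type lists. All 20 members of the pan-T list exceeded 10 TPM, with a list mean of 7.54 ± 0.035 on the log2(TPM + 1) scale (SD, n = 4). The constant regions of the T cell receptor led it, with Trbc2 at 658 ± 19.5, Trac at 501 ± 21.6 and Trbc1 at 435 ± 12.2 TPM. Tcf7, a transcription factor of T cell identity, had 431 ± 11.2 TPM, Lck, the kinase that starts receptor signalling, 313 ± 5.80 TPM, and Cd3e, a chain of the CD3 complex, 302 ± 3.86 TPM. Cd3e lies on chromosome 9 between 44998740 and 45009627 and Lck on chromosome 4 between 129548344 and 129573641 in mm10. The lists of other spleen cells were lower in every library. The pan-T list exceeded the B cell list by 5.58 ± 1.09 on the log2 scale, the monocyte and macrophage list by 5.96 ± 0.119, the natural killer list by 6.23 ± 0.130 and the erythroid list by 5.82 ± 0.866 (SD, n = 4). Each difference had the same direction in 4 of 4 libraries, and each gave p = 0.125 in an exact two-sided sign-flip permutation test, the smallest p that 4 libraries allow, so no test of this kind could pass 0.05. Over the 7 such tests made, the Benjamini-Hochberg adjusted p of each exact permutation test was also 0.125.

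The other lists had few abundant members. In the monocyte and macrophage list 8 of 14 genes reached 1 TPM, led by Lyz2, a lysozyme of myeloid cells, at 15.4 ± 0.603, Hmox1 at 5.29 ± 0.921 and Cd68 at 4.26 ± 0.653 TPM. In the natural killer list 5 of 10 reached 1 TPM, with Il18rap at 6.38 ± 0.221, Tyrobp at 5.60 ± 1.64 and Fcer1g at 3.40 ± 0.665 TPM. The list also holds Klra receptor genes, whose near-identical copies differ between strains and are uncertain. The list means were 0.995 ± 0.188 for dendritic cells, 1.12 ± 0.056 for platelets, 0.956 ± 0.252 for plasma cells and 0.790 ± 0.044 for stroma and endothelium. In each of these lists 1 gene stood far above the rest, namely Ccr9 at 18.1 ± 1.32, Itgb3 at 29.7 ± 1.10, Xbp1 at 33.3 ± 2.75 and Pecam1 at 54.5 ± 4.75 TPM. The next member in each was much lower, at 1.45 ± 1.30 TPM for Bcl11a, 6.43 ± 1.21 for Itga2b, 2.06 ± 0.401 for Prdm1 and 0.205 ± 0.0238 for Cdh5. Tnfrsf17, a plasma cell receptor, had no counts in any library, where 3 counts, the limit that a count of 0 allows, correspond to between 0.174 and 0.206 CPM (counts scaled to library size). Such floors cover counting error only.

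**Figure D1:**
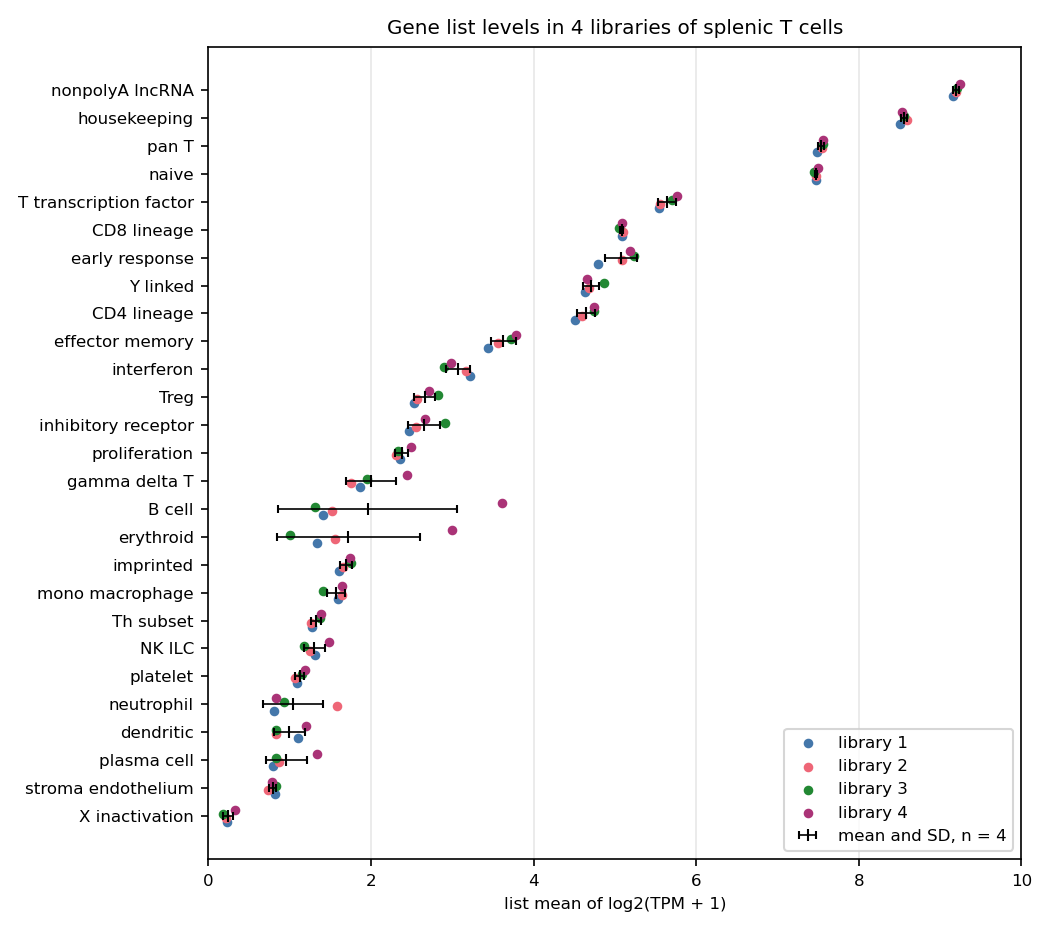
Mean of log2(TPM + 1) over the members of each gene list (horizontal axis), with 1 coloured point per library and a black bar for the mean and SD of the 4 libraries. The pan-T list lies at 7.54, whereas the B cell and erythroid lists lie at 1.306 to 1.522 and near 1.0 to 1.6 in libraries 1 to 3 and at 3.61 and 3.00 in library 4.

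Both T cell lineages were present. Cd8a and Cd8b1, the chains of the CD8 co-receptor, had 123 ± 9.13 and 113 ± 9.93 TPM, and Runx3, a transcription factor of CD8 cells, 49.5 ± 4.42 TPM. Cd4, the co-receptor of helper cells, had 85.2 ± 6.54 TPM, its lineage factor Zbtb7b 30.2 ± 3.24 and Cd40lg, a helper ligand, 25.8 ± 4.67 TPM (SD, n = 4). The CD8 list mean was 5.08 ± 0.020 and the CD4 list mean 4.65 ± 0.111. The log2 ratio of Cd4 to Cd8a was -0.53 ± 0.216, with values of -0.72, -0.59, -0.22 and -0.57 in libraries 1 to 4 and an exact two-sided permutation p of 0.125. Of the beta constant regions, Trbc2 exceeded Trbc1 by 0.60 ± 0.015 on the log2 scale in 4 of 4 libraries, with the same exact permutation p. These genes share near-identical exons, so the ratio is uncertain. Genes of gamma-delta T cells were much lower than Trac. Tcrg-C4 had 7.22 ± 1.22, Trdc 5.84 ± 0.799 and Tcrg-C2 5.08 ± 1.52 TPM, and the list mean was 2.00 ± 0.303. The list mean was highest in library 4, where 5 of 5 tested members lay above their mean. Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4 stood there at 1.29, 1.29, 1.65 and 1.33 times the mean of the others, and Blk, a kinase that B cells also express, at 4.12 TPM against 0.32 to 0.62.

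Most annotated variable segments of the alpha and beta chains had counts in every library. All 22 annotated Trbv segments had counts in every library, with 2571 ± 274 counts in total. Trbv29 led by TPM with 75.8 ± 5.93, followed by Trbv13-2 with 62.2 ± 7.53, Trbv1 with 44.0 ± 3.50, Trbv13-1 with 36.6 ± 3.57 and Trbv5 with 36.0 ± 3.77 TPM, and these 5 took 42.9% ± 1.82 of Trbv counts (SD, n = 4). Across segments, which are not independent replicates, the shares of any pair of libraries correlated at r = 0.963 to 0.984. Of 108 Trav segments, 94 had at least 1 count in every library, with 2190 ± 229 counts in total, and the shares correlated at r = 0.834 to 0.882 between libraries. With fewer counts per segment than for Trbv, counting error alone lowers this r. Trav7-2 led with 21.8 ± 1.48 TPM, then Trav6-5 with 14.4 ± 2.20, Trav9-1 with 13.8 ± 3.80, Trav1 with 13.2 ± 1.48 and Trav12-2 with 13.2 ± 1.53 TPM. Many Trav segments are near-identical duplicates, and the reference is that of C57BL/6, so the shares of single Trav segments are uncertain. In the second deposited quantification Trav7-2 was listed at 0 and Trav9-1 at 4.60 TPM, and Trav7d-2 led with 28.9 TPM, where the first gave it 0.103. Among Trbv segments Trbv13-2 led there with 108.9 TPM, ahead of Trbv29 with 68.8.

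**Figure D2:**
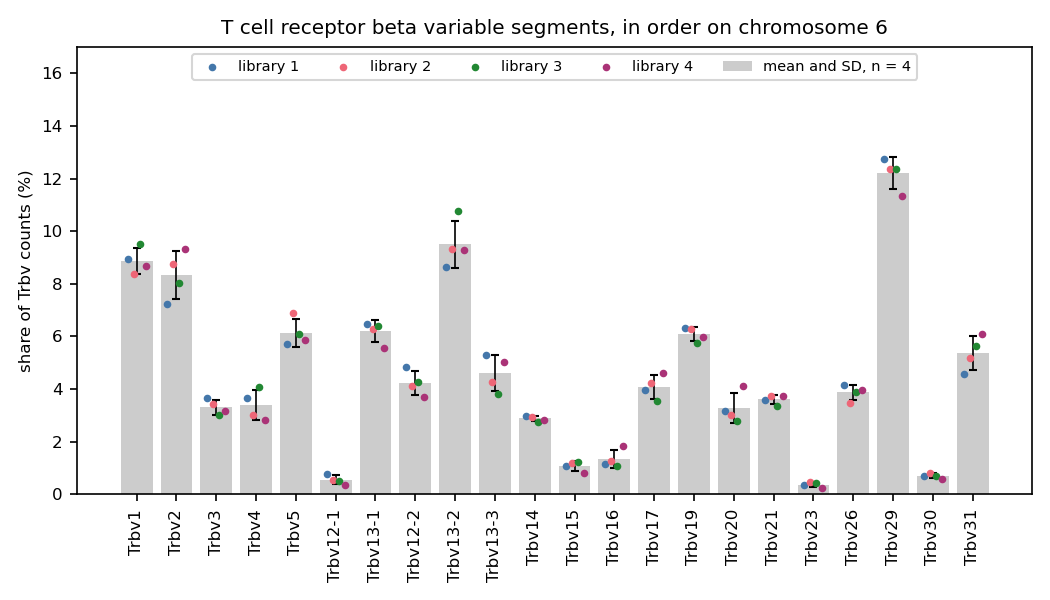
Share of all Trbv counts (vertical axis, percent) taken by each variable segment, in order along chromosome 6, as bars for the mean, error bars for the SD of 4 libraries and a point per library. Trbv29 and Trbv13-2 have the tallest bars and every segment has counts in each library.

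Genes of naive T cells stood well above those of effector and memory cells. All 12 members of the naive list exceeded 10 TPM. Besides Tcf7, they included Klf2 at 343 ± 15.04, Satb1 at 325 ± 10.5, Lef1 at 236 ± 13.9 and Foxp1 at 232 ± 29.2 TPM. The effector and memory list had 10 of 16 members above 10 TPM. Il2rb had 55.3 ± 2.86, Id2 54.4 ± 2.19, Ccl5 51.1 ± 17.6, Nkg7 48.9 ± 3.90, Gzma 32.4 ± 1.08 and Cd44 20.7 ± 2.22 TPM. The naive list exceeded the effector and memory list by 3.85 ± 0.151 on the log2 scale (SD, n = 4), in 4 of 4 libraries, with an exact two-sided permutation p of 0.125. The chemokine Ccl5 differed between libraries by more than genes of its abundance usually do, from 32.2 TPM in library 1 to 73.1 TPM in library 3.

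Regulatory T cell genes were measurable. Foxp3, the defining transcription factor, had 9.21 ± 0.899 TPM and lies on chromosome X between 7573644 and 7595245. Ctla4, an inhibitory receptor, had 20.3 ± 4.90, Tnfrsf18 16.1 ± 0.814, Ikzf2 15.8 ± 4.55, Il2ra 8.73 ± 1.29 and Lrrc32 3.28 ± 0.106 TPM, and the list mean was 2.66 ± 0.135. Helper subset genes were low apart from Gata3 at 22.7 ± 2.38 TPM, with Tbx21 at 5.09 ± 0.313 and Ifng at 4.79 ± 1.24 TPM and a list mean of 1.32 ± 0.066. Il17a had no counts in any library. Inhibitory receptor genes had a list mean of 2.65 ± 0.195, led by Btla at 22.4 ± 1.51 TPM, Ctla4 and Tox, a factor of this list that is not itself a receptor, at 16.9 ± 2.74 TPM. The transcription factor list had a mean of 5.64 ± 0.111, with Ets1 at 283 ± 7.07, Ikzf1 at 208 ± 3.31 and Bach2 at 103 ± 7.67 TPM.

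Early response genes, which cells switch on within minutes of stimulation or handling, had a list mean of 5.08 ± 0.198. Junb had 383 ± 49.7, Jund 271 ± 11.6 and Jun 143 ± 9.64 TPM. Of 15 tested members, 3 (Fos, Fosb and Hspa1b) varied more between libraries than the trend (one-sided Fisher's exact test, adjusted p = 0.00725 over the lists), and 5 did when adjusted over the list alone. Fos stood at 57.6, 83.1, 117.0 and 141.4 TPM in libraries 1 to 4. The list deviated by -0.28 on the log2 scale in library 1, below all 10000 random lists matched on expression. The interferon list had a mean of 3.07 ± 0.148, with Bst2 at 20.9 ± 1.22 and Irf7 at 15.97 ± 3.03 TPM, and none of its 12 tested members passed the test over all genes or over the list alone. As a list it deviated by 0.181, 0.136, -0.22 and -0.097 on the log2 scale in libraries 1 to 4, each outside the central 95% of random lists, with an adjusted p of 0.0162, 0.0371, 0.0384 and 0.129 (permutation test against random lists, over 96 deviations). Proliferation genes had a mean of 2.38 ± 0.081. The replication factors Pcna, Mcm2 and Mcm5 had 80.6 ± 11.3, 21.5 ± 2.22 and 20.4 ± 1.52 TPM, whereas Mki67, a marker of dividing cells, had 2.54 ± 0.338 TPM. The Y chromosome genes Eif2s3y, Ddx3y, Uty and Kdm5d had 42.4 ± 3.56, 33.8 ± 3.60, 17.5 ± 4.05 and 16.2 ± 1.33 TPM, and Xist, the RNA of the inactive X chromosome, had 0.0225 ± 0.0126 TPM. The pair Xist and Tsix had a list mean of 0.238 ± 0.059. Among 20 imprinted genes, 9 reached 1 TPM, led by Zrsr1 at 31.9 ± 3.24, Impact at 18.6 ± 2.02 and Igf2r at 14.5 ± 1.90 TPM, and the list mean was 1.69 ± 0.070. The files do not separate the maternal from the paternal allele.

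The 4 libraries were close to each other. The median Pearson correlation across genes was 0.971 over the 6 pairs, from 0.966 for libraries 1 and 4 to 0.976 for libraries 2 and 3. Genes are not independent replicates. No pair agreed within counting error, with a chi-square per degree of freedom from 4.42 for libraries 2 and 3 to 10.1 for libraries 1 and 4, so no pair was merged. This covers counting error only and does not show that the libraries are separate samples. Of 13118 tested genes, 183 varied between libraries more than genes of their abundance usually do, in edgeR's goodness-of-fit test at a Benjamini-Hochberg adjusted p below 0.05, and 603 had an unadjusted p below 0.05. Library 4 was the farthest from the mean for 100 of them, above it for 73 and below it for 27. Leaving out library 4 gave 116 genes, of which 85 were among the 183, and leaving out library 1 gave 118, of which 113 were.

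B cell genes were the clearest group. Of 10 tested members of the B cell list, 9 passed, against 0.14 expected from the share of all genes (one-sided Fisher's exact test, adjusted p = 4.38e-15 over 27 lists), and 10 passed when adjusted over the list alone. All 15 members had their highest TPM in library 4, so the calls follow 1 library and are not independent, as Fisher's test assumes. Igkc, the kappa light chain, had 67.9 TPM in library 4 and 6.23 ± 0.901 in the others (SD, n = 3), Cd79a, a chain of the B cell receptor complex, 12.6 against 1.36 ± 0.157, Cd79b 11.8 against 1.78 ± 0.532, Ighd 16.5 against 2.70 ± 0.630, Cd22 12.8 against 2.71 ± 0.789, and Pax5, the B cell identity factor, 9.19 against 0.537 ± 0.315 TPM. Ighm, the heavy chain of IgM on chromosome 12 between 113418558 and 113422730, was abundant in every library, at 190.7 TPM in library 4 and 140 ± 3.97 in the others. The list deviated by 2.24 on the log2 scale in library 4, above all 10000 random lists. Without library 4 the pan-T list exceeded the B cell list by 6.12 in place of 5.58. Cd74, the invariant chain of MHC class II, had 149.5 TPM in library 4 against 28.9 ± 4.67 in the others.

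Erythroid and neutrophil genes varied as well. Hba-a1 and Hba-a2, the alpha globins, and Hbb-bs, a beta globin, had 246.5, 155.8 and 194.9 TPM in library 4, against 6.42 to 26.6, 3.69 to 15.2 and 4.22 to 18.2 in the others. Globin genes have near-identical copies, so the split between them is uncertain. Of 4 tested erythroid genes, 3 passed over all genes (one-sided Fisher's exact test, adjusted p = 9.52e-05) and as many over the list alone, and the list deviated by 2.53 in library 4. Library 2 had the highest TPM for 9 of 12 neutrophil genes. S100a9 and S100a8, the calprotectin subunits, had 13.3 and 11.4 TPM there, 3.59 and 3.67 times the mean of the others, whereas Mmp9 was highest in library 1, at 2.92 TPM against 2.67 in library 2, and had 2.00 ± 0.937 TPM over the 4 libraries. The neutrophil list had a mean of 1.04 ± 0.366 and deviated by 1.14 in library 2, with 3 of 4 tested members passing over all genes (adjusted p = 9.52e-05 in the same test) and as many over the list alone. The erythroid calls follow library 4 and the neutrophil calls library 2, so Fisher's test again counts dependent genes. The erythroid list mean was 1.72 ± 0.880 and the B cell list mean 1.96 ± 1.10 over the 4 libraries.

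The other genes with the largest statistics belonged to no list. Gm24497, a small nuclear RNA with similar copies and therefore uncertain, ranged from 467 to 4170 TPM and was listed at 0 in every library in the second quantification. Lars2, the mitochondrial leucyl-tRNA synthetase on chromosome 9, had 674 TPM in library 1 and 207.6 to 288 in the others. The mitochondrial gene mt-Co3 ranged from 89.6 to 470.5 TPM, and nuclear copies of mitochondrial sequence make it uncertain. Its mean was 268 ± 166.5 TPM in the first quantification and 1053 ± 249.5 TPM in the second (SD, n = 4), a smaller SD relative to the mean. Slc15a2, a peptide transporter, had 29.4, 9.73, 2.40 and 29.5 TPM in libraries 1 to 4, and Tspan10, a tetraspanin, had 29.5 TPM in library 3 and 3.65 to 4.07 in the others. In the remaining lists, Ctla4 among regulatory and inhibitory receptor genes, Bcl11a among dendritic genes, Blk among gamma-delta genes and Kcnq1ot1 among imprinted genes each passed. Adjusted over the list alone, 2 inhibitory receptor and 2 dendritic genes did. No member of the pan-T, CD4, CD8, naive, monocyte and macrophage, natural killer, proliferation, transcription factor, housekeeping, or Y-linked lists passed over all genes or over the list alone. Of 96 deviations, 24 lists in 4 libraries, 33 in 14 lists lay outside the central 95% of random lists, and 19 of them in 10 lists had an adjusted p below 0.05 (permutation test against random lists). The 4 deviations of a list sum to 0, so a large value in 1 library pushes the others out, as for the B cell and erythroid lists, and these counts are not of separate events. Besides the lists above, these were the inhibitory receptor and regulatory lists at 0.328 and 0.212 in library 3. Also among them were the monocyte and macrophage and dendritic lists at -0.248 and -0.374 in library 3, and the gamma-delta list at 0.628 in library 4. Without Blk, at 1.95, the 4 receptor genes of the gamma-delta list gave 0.299. That is below 0.38, the upper limit of random lists for all 5 members, and was not tested itself. The transcription factor list deviated by -0.051, -0.072, 0.039 and 0.084 in libraries 1 to 4, outside the range in libraries 1, 2 and 4 with adjusted p of 0.088, 0.0680 and 0.0680, and 7 of its 13 members were highest in library 4 by TMM-scaled counts, against all 13 by TPM. Members of a list that vary together leave the range of random lists more easily than unrelated genes.

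**Figure D3:**
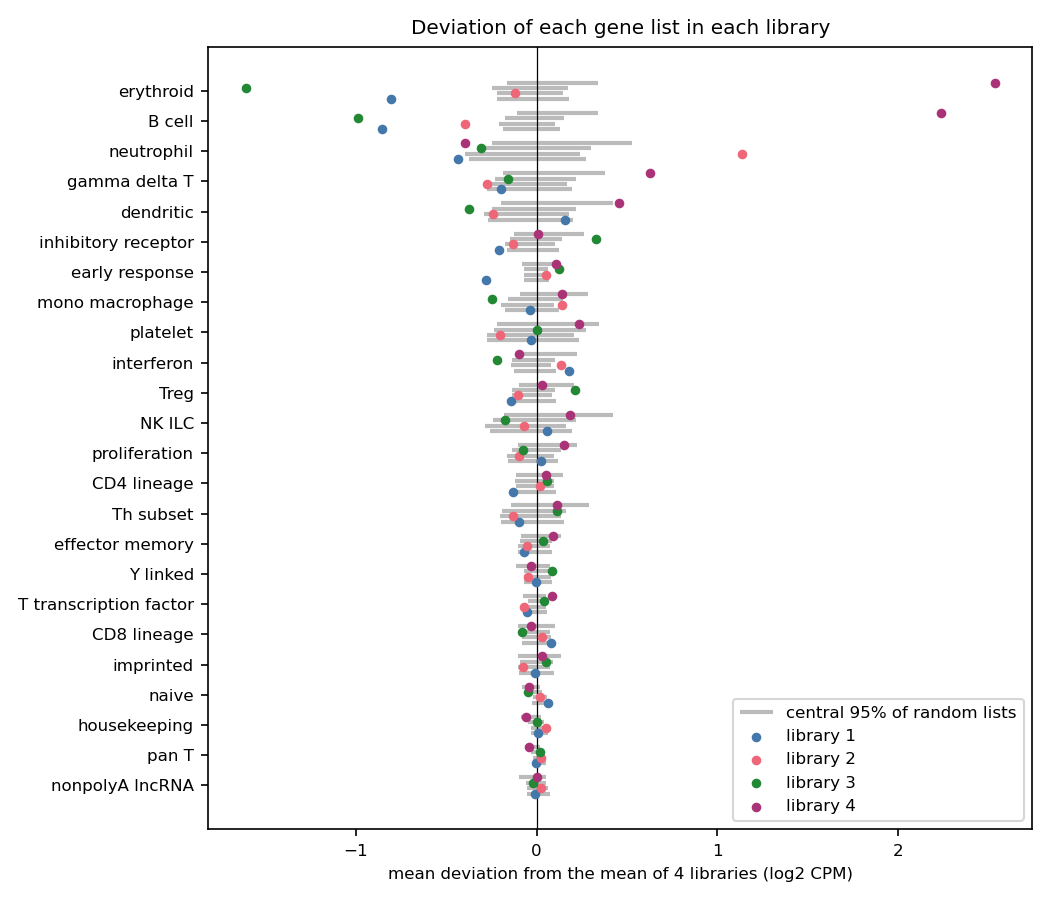
Mean deviation of each gene list in each library from the mean of the 4 libraries, in log2 CPM (horizontal axis), as coloured points, with grey bars for the central 95% of 10000 random lists matched on size and expression. The erythroid and B cell lists reach 2.53 and 2.24 in library 4 and the neutrophil list 1.14 in library 2, all outside the grey bars.

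Transcript shares were estimated for 16 genes with known isoforms. Ptprc encodes CD45, a phosphatase whose variable exons are skipped in different T cell states, and had 540 ± 30.7 TPM. Its main annotated transcript was Ptprc-203 with 28.1% ± 2.32 of the gene's TPM (SD, n = 4), followed by Ptprc-213 with 21.1% ± 0.744. Ptprc-203 lacks 3 exons of the longer Ptprc-207, on chromosome 1 at 138117754 to 138117894, 138120020 to 138120166 and 138122456 to 138122584 in mm10. The second deposited quantification gave Ptprc-203 a share of 25.0% ± 2.71, and it had the same main transcript as the first for 11 of the 16 genes. Cd3e-201 held 88.2% ± 1.68 of Cd3e, Ctla4-201 83.7% ± 2.85 of Ctla4, Tcf7-201 79.3% ± 0.573 of Tcf7 and Cd247-201 77.5% ± 1.84 of Cd247, which had 135 ± 1.98 TPM. Runx3-201, Il2ra-201 and Lck-202 held 69.9% ± 4.47, 62.5% ± 7.26 and 60.3% ± 4.06 of their genes, and Cd44-203 and Lef1-201 42.2% ± 3.61 and 40.2% ± 3.14. For Ikzf1, Runx1, Foxp1, Fyn and Foxp3 the 2 quantifications named different main transcripts. Runx1-204, for example, held 28.6% ± 4.15 in the first and was listed at 0 in the second. Across genes, the 2 quantifications correlated at a median r of 0.844 per library.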

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

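Of the tests in this part, the B cell gene test without a filter, the scaling test, the wrong-label test and the quantifier test were chosen after the result was seen. A value was singled out where 1 library lay far from the other 3 (Dixon's criterion at 95%). Of 168 gene levels, list levels, shares and differences, 25 met this, and 16 of the 25 were high values of library 4. Chance gives about 8.4 for independent values not chosen by their spread. The values are not independent, since lists and differences hold the same genes. Cd74, Pax5 and Tspan10, all flagged, were named only because they varied most between these libraries. The 8.4 is therefore no measure of chance for this set. B cells in the preparation are weighed here as a technical explanation, reads from another cell type. No biological explanation was tested, because the design has 1 group.

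The largest set was in library 4, of B cell genes and of a few genes outside that list. The B cell list mean was 3.608 there against 1.306 to 1.522 in the others, the pan-T minus B cell difference 3.955 against 6.021 to 6.251, and the plasma cell list mean 1.331 against 0.788 to 0.867. Single genes were Igkc at 67.9 TPM, Ighd at 16.5, Cd22 at 12.8, Cd79a at 12.6, Cd79b at 11.8, and Pax5 at 9.19 TPM. Outside the B cell list, Bcl11a of the dendritic list stood at 3.40, Mzb1 of the plasma cell list at 2.94 and Cd74, on no list, at 149.5 TPM.

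The pan-T list deviated by -0.043 (log2) in library 4. That value was taken after TMM scaling, which removes a shift shared by most genes, so it cannot decide on scaling or depth. The B cell list deviated by 2.24 on the same scale, so B cell genes rose relative to the pan-T list in library 4. Another cell type under a wrong label would have lost T cell genes, but the pan-T list mean in library 4 was 0.035 above that of the others. B cells in the preparation remain a hypothesis, and selection for CD3, the marker in the sample label, would remove most of them, though the sources name no selection method. In the test set beforehand, 8 of 20 further B cell genes passed the count filter, and their median difference of 0.53 (log2, 95% bootstrap interval 0.29 to 1.09) lay between the bounds of 0.5 and 1 and decided nothing. Because that filter removes genes high in a single library, the test was repeated after this value was known on all 20 genes with no filter, which gave 2.10 (1.09 to 2.71) with 20 of 20 higher in library 4. The hypothesis rests on this later version. Of the 20 genes, 10 had a mean of at least 1 TPM over libraries 1 to 3, 7 of the 8 in the first test among them. Such a baseline could hide a small share. Neither bootstrap interval measures the spread between libraries, because a single library was set against the others. Genes that move together in that library are not replicates of it.

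Ighm was high in every library, and highest in library 4 at 190.7 TPM against 135.3 to 142.4. If B cells supplied it throughout, immunoglobulin variable segments would stand to Ighm in libraries 1 to 3 as they do in the excess of library 4. Summed over 113 IGHV segments, the ratio was 0.0330 in libraries 1 to 3 and 0.660 in that excess, a ratio of ratios of 0.0499 where B cells would give 0.5 to 2. This argues against B cells as the main source of Ighm in libraries 1 to 3. The argument takes the excess of library 4 as coming from B cells, which remains a hypothesis. Assignment by the first quantification alone is argued against as well, since Ighm in the second quantification relative to the first was 0.889 of the median of 543 protein-coding genes of similar level. What supplies Ighm RNA in these libraries stays open, and transcription of the constant region without a rearranged variable segment was not tested.

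The remaining values are given without an explanation. In library 4, Hba-a1 had 246.5 TPM against 6.42 to 26.6 in the others, Hbb-bs 194.9 against 4.22 to 18.2, Hba-a2 155.8 against 3.69 to 15.2, Trdc 7.03 against 5.33 to 5.59, and Trbv29 67.0 against 77.6 to 79.7 TPM. In library 2, S100a9 had 13.3 TPM against 3.25 to 4.30, S100a8 11.4 against 2.21 to 3.58, the neutrophil list mean was 1.583 against 0.809 to 0.928, and Bach2 had 91.1 TPM against 105.3 to 107.3. In library 3, Tspan10 had 29.5 TPM against 3.65 to 4.07, Cd8a 109.2 against 126.2 to 128.4, and the difference of the pan-T and the monocyte and macrophage lists was 6.142 against 5.897 to 5.915.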

How the results depend on the processing

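Of 125 recomputed values, none changed sign, though the counts and shares among them cannot be negative, so for these that was certain. Of the 61 judged by their spread (1 SD, or the SE over members for list deviations) or by 1.5 times a count, 48 stayed within it and 13 moved, and except for leave-one-out values and low-count filters the cause was not tested. The other 64 are list differences and ratios, whose sign-flip test cannot pass 0.05 with 4 libraries or fewer, so staying on the same side of it was certain. Their direction held in each setting, but 17 of the 64 lay beyond 1 SD of the reported value, none of them a leave-one-out value. Over all settings the log2 difference of the pan-T list from the B cell list ran from 4.343 to 6.416, from the monocyte and macrophage list from 4.687 to 6.743, from the natural killer list from 4.787 to 7.454 and from the erythroid list from 4.078 to 7.198, and the naive minus effector and memory difference from 3.296 to 4.111, so the sizes of these differences depend on the pseudocount. Keeping members with a mean of at least 1 TPM left the B cell difference at 5.577 and gave 5.251, 5.212, 4.078 and 3.655 for the others in that order. The log2 ratio of Cd4 to Cd8a ran from -0.629 to -0.407 and that of Trbc2 to Trbc1 from 0.498 to 0.603. The median replicate correlation was 0.932 with a pseudocount of 0.1 and 0.990 over all genes with no filter. The mitochondrial share was 6.19% of TPM. The ribosomal protein genes named Rpl or Rps plus a number held 19.1% of the TPM of protein-coding nuclear genes, a smaller denominator, and 9.57% in the second quantification. The count of variable genes was 279 with no filter on 23727 genes (145 of them among the 183) and 353 with a common dispersion (147 shared), and ran from 116 without replicate 4 to 146 without replicate 3, with 118 without replicate 1. The correlation between quantifications was 0.748 with a pseudocount of 0.1 and 0.966 over protein-coding genes. The Ptprc-203 share was 25.0% in the second quantification. The B cell deviation in library 4 was 2.029, 2.105 and 1.881 without replicates 1, 2 and 3, against 2.24. Part of each fall is arithmetic, because library 4 then weighs more in the mean it is compared with. Detected genes ranged from 8084 at 5 TPM to 15495 at 0.1 TPM, and were 10832 with TPM rescaled to protein-coding and receptor genes, a setting chosen after seeing the data. List deviations of library 4 have no value without replicate 4. No paired analysis was possible between groups, because there is 1 group; the sign-flip tests pair gene lists within a library. Genes below about 3 counts cannot be told from 0 at this depth.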

Other observations

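The genes in this part were chosen after their values were seen, and no explanation was tested. Of 10 genes of MHC class II and its partners, all 10 had their highest TPM in library 4 and 7 varied more than the trend, with H2-Ab1 at 54.2 TPM in library 4 and 8.26 on average in the others, H2-Aa at 39.1 against 8.92 and H2-Eb1 at 32.2 against 6.71. H2-DMa, H2-Oa and H2-Ob did not pass, at 1.22, 1.62 and 1.61 times the mean of the others. The granzyme Gzmk had 0.15, 0.47, 4.03 and 2.15 TPM in libraries 1 to 4, on 2 to 62 counts in libraries 1 to 3. The heat shock gene Hspa1b had 0.58 TPM in library 1 and 2.53 to 3.51 in the others. Gm42418, annotated as a long non-coding gene, was high in library 1, as Lars2 was, at 17071 TPM against 10656 to 11737.

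The share of genes called variable differed between gene classes. By class, small nucleolar RNAs made 8 of the calls among 63 tested (12.7%, two-sided Fisher's exact test, p = 2.48e-06), and genes of the annotation class TEC, loci that await experimental evidence, 23 among 758 (3.03%, p = 5.73e-04), against 117 among 10848 protein-coding genes (1.08%). Processed pseudogenes made 15 among 416 (3.61%, two-sided Fisher's exact test, p = 7.31e-04), immunoglobulin constant genes 2 of 3 (p = 5.75e-04) and lincRNAs 2 of 242 (0.826%, p = 0.778). These p-values were not adjusted over the classes, and Fisher's test counts genes as independent. Genes of a class can move together, as Igkc and Ighd did in library 4, so the p-values are not reliable there. The median deviation of the 758 genes of the TEC class was -0.10, -0.19, 0.12 and 0.20 on the log2 scale in libraries 1 to 4. The median log2 ratio of retained-intron to protein-coding transcripts over 3471 genes was -1.19, -1.20, -1.11 and -1.09 in the same order. Olfactory and vomeronasal receptor genes, which T cells are not known to use, had 52.1, 46.4, 47.0 and 54.7 CPM relative to protein-coding counts. These are 3 sets of values for 4 libraries, too few for a correlation.

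The 2 quantifications differed by gene class. Of 6441 genes at 10 TPM or more in the first, 198 were listed at 0 in every library in the second, among them 72 small nucleolar and 35 small nuclear RNAs. Of 5908 protein-coding genes at that level, 0.949% lay beyond 2-fold of the median ratio.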
